A study of Homo sapiens with 2 samples.

How the data were processed

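Total RNA of human mesenchymal stem cells cultured for 5 days on plain or ECM-coated gelfoam was measured on 2 Affymetrix 3′ expression arrays of the human U133 Plus 2.0 design, 1 per condition. Per the labels' protocols, biotin-labelled RNA was prepared with a 3′ in vitro transcription kit, which primes at the poly-A tail, so signal weakens towards the 5′ end of a transcript when RNA is degraded. The extraction text in the labels speaks of RNA from bone of the skull, whereas titles and culture labels describe cells on gelfoam. The culture labels were followed here, and the mismatch was left open. The labels do not state whether both cultures came from the same donor, how many cultures went into each RNA sample or when the arrays were run.

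The authors deposited 1 linear intensity (signal) per probe set and array. Per the submitters' processing notes, MAS5 and Affymetrix Expression Console were used, with versions and background settings not given in the sources used here. The deposited intensities had equal 2% trimmed means (500.1 on both arrays), which is the MAS5 scaling. Values ranged from 0.12 to 60234 on gelfoam and from 0.11 to 59565 on ECM gelfoam. MAS5 summarises each probe set on its own array and leaves dim probe sets noisy, so ratios between dim signals are unstable. Detection calls were not used here. Precision was limited by the number of arrays, 1 per group.

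Probe sets were named through the platform's annotation table. Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several symbols and 11721 were unnamed in the table. Symbols were brought up to date through Entrez identifiers in a RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 41037 of the 41091 probe sets matched a current gene. Control probe sets and those with several symbols or none were left out of gene values, as were 35 sex-linked genes, since the cells came from donors. The remaining 19740 genes were each represented by the probe set with the highest mean log2 signal over both arrays. Probe sets whose identifier ends in _s_at or _x_at can bind several transcripts. Genes represented by such probe sets, or by paralogs of near-identical sequence such as the IFITM, FABP and HLA families, are uncertain.

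Signals below a floor of 89.6, the median of all probe sets of both arrays, were raised to it, and a gene was measured when it passed the floor on at least 1 array (13236 genes). The log2 ratio of ECM gelfoam over gelfoam was then taken, and a gene was counted at 2-fold or more, the threshold the series states. A fold whose dimmer side lay under the floor is a lower bound. No test was made, since there was 1 array per group. As the only available spread, the SD of log2 ratios between measured probe sets of the same gene was pooled over 6387 genes (0.52). It covers disagreement within these 2 arrays and no variation between cultures.

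A set of 32 gene lists was fixed before the data were examined, as were the floor, the rule for naming genes and 13 alternative settings. Each list was described by its members at least 2-fold apart and by its median log2 ratio, with the percentile of that median among 10000 random lists of the same size, matched on mean log2 signal in 20 bins. The 95% range of these random lists and the upper end of their counts of 2-fold genes are the yardsticks printed. After the results were seen, each list was also set against random lists drawn under each alternative setting. A percentile describes these 2 arrays and is not a test of the conditions. Adding a constant to all log2 ratios leaves a list's standing among its random lists unchanged. Some genes belong to several lists, such as VEGFA (secreted factors and hypoxia), VCAM1 (inflammation and stromal surface) and IGFBP3 (senescence and growth factor binding). The genes named were the 12 highest and 12 lowest ratios (clone-like, antisense and open reading frame names left out), up to 4 members at least 2-fold apart in each list, or the 2 brightest if there was none, and 14 genes of bone formation given whatever their values. Further list members were named as examples after their values were seen.

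The counting and list steps were tested on simulated data for this comparison, with 13236 genes and noise at the SD between probe sets. Of genes given a 2-fold difference 59% were called, and of genes given an 8-fold difference 98%, while 4.76% of unchanged genes were called. Of unchanged lists of 25 genes 5% lay outside the random range, and all lists with a shift of 1 on the log2 scale lay above it, with a mean median of 0.92. The unchanged lists were themselves random genes with independent noise of 1 size, so their 5% follows from the design. The simulation does not cover lists of co-regulated genes or the larger noise of dim probe sets.

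Alternatives changed the floor (25th or 75th percentile, none with or without a filter on mean signal, or a pseudocount of 22.4), the scaling (quantile normalization, trimmed mean, centring on housekeeping genes or on all measured genes, removal of a loess trend with a span of 0.3), the handling of several probe sets (mean or median of log2 ratios) and probe sets marked as shared (left out). Centring on the bacterial poly-A controls (median of their 3′ probe sets), RNAs normally spiked into the sample before labelling, was added after seeing the data. RNA quality was read from the ratio of 3′ to 5′ signal of the GAPDH and ACTB control probe sets. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots matplotlib 3.10.9.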

Results

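Transcript levels were measured in osteogenically enhanced human mesenchymal stem cells (OEhMSCs), adult stromal cells prepared to favour bone formation. The cells were cultured for 5 days on gelfoam, a gelatin sponge used as a scaffold. The sponge was either plain or coated with extracellular matrix (ECM) made by mesenchymal stem cells. Each condition was measured on 1 array, so the data comprised 2 arrays, called gelfoam and ECM gelfoam here. The comparison addressed whether the matrix coating goes with higher expression of secreted osteogenic factors, and the series set a 2-fold threshold for it. Both arrays held 54675 probe sets, scaled to trimmed means of 500.1 each. Median signals were 77.5 on gelfoam and 101.9 on ECM gelfoam, and the highest signals were 60234 and 59565. A floor of 89.6, the median of both arrays pooled, was passed by 47.2% of probe sets on gelfoam and 52.8% on ECM gelfoam. With 1 array per group there was no replicate error, no test and no p-value. Each fold below is the ratio of these 2 arrays only, and "at least" marks a fold whose dimmer side lay under the floor.

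The genes brightest on ECM gelfoam relative to gelfoam included matrix, cell cycle and signalling genes. Genes are given by symbol, and the signal of the brightest probe set stands for each. KANK4, an adaptor that links adhesions and the cytoskeleton, was at least 52.1-fold higher on ECM gelfoam (signal 4671 against 21.9). The cell cycle inhibitor CDKN2B was 16.8-fold higher (7531 against 447.8), and the cartilage matrix protein gene COMP 17.0-fold higher (2109 against 123.9). NOX4, an oxidase induced by TGF-beta, was 13.2-fold higher, and the fatty acid binding protein gene FABP4 at least 13.8-fold higher. The others among the 12 highest ratios were ST6GAL2 (at least 26.8-fold), ANO1 (at least 17.7-fold), PLXDC1 (17.0-fold), RASL11B (13.6-fold), MIR181A2HG (at least 8.48-fold), DKK2 (8.26-fold) and FOXS1 (at least 8.12-fold). Probe sets of PLXDC1 disagreed, with log2 ratios from -0.17 to 4.09, those of NOX4 lay between 0.92 and 3.72, and the second probe set of ST6GAL2 stood at 1.64.

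The genes dimmest on ECM gelfoam relative to gelfoam were led by interferon-induced genes. IFI27 was at least 61.0-fold lower on ECM gelfoam (57.5 against 5461), IFI6 39.2-fold lower (717.5 against 28161), MX1 29.8-fold lower, IFI44L at least 27.5-fold lower and IFIT1 21.5-fold lower. IFITM1, of the same family of responses, was 43.2-fold lower by a probe set marked as shared between related transcripts. CHI3L1, a secreted chitinase-like glycoprotein, was 40.3-fold lower (513.7 against 20727), and 2 innate immune recognition genes, COLEC12 and PTX3, were 31.9-fold and 29.0-fold lower. ADM, which encodes the vasodilator peptide adrenomedullin, was 29.2-fold lower (359.8 against 10511). CLDN11 and DEPP1 completed the 12 lowest ratios at 23.3-fold and 20.7-fold lower, although a further probe set of each gave only -0.87 and -1.11 on the log2 scale.

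Of 13236 measured genes, 689 (5.21%) were at least 2-fold higher on ECM gelfoam and 694 (5.24%) at least 2-fold lower, while 11853 lay within 2-fold. Larger differences were more often towards lower signal: 86 genes were at least 4-fold higher and 147 lower, and 13 were at least 8-fold higher and 43 lower. The dimmer side was under the floor for 129 of the higher and 109 of the lower genes. Over all measured genes the median log2 ratio of ECM gelfoam over gelfoam was 0.02, and Pearson's r between the log2 signals of the arrays was 0.94 across genes, which are not independent replicates. The split depended on the scaling: it was 506 higher and 883 lower after quantile normalization and 496 higher and 892 lower after removal of a loess trend. Centring on the spiked bacterial poly-A controls, chosen after seeing the data, moved the median of all measured genes to -1.53, the split to 31 higher and 11115 lower, 470 of the 689 higher genes below 0, and all 32 gene list medians below 0. Directions below are therefore relative to the scaling of the deposited signals. Where gelfoam lay under the floor, as for 129 of the 689 higher genes, a value centred on the poly-A controls is a lower bound. Such a value below 0 leaves the sign open.

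The only spread available for a single gene was that between probe sets of the same gene, whose log2 ratios had a pooled SD of 0.52 over 6387 genes. Noise of that size alone would put 5.34% of unchanged genes (707 of the measured ones) past 2-fold, a number that is not small beside the counts observed. Among the 295 higher genes with a second measured probe set, that probe set was also 2-fold higher for 108 (36.6%), had the same sign for 264 and was 2-fold lower for 3. Among the 343 such lower genes, the second probe set was 2-fold lower for 117 (34.1%), had the same sign for 276 and was 2-fold higher for 5. Of the genes named by rule, 46 were at least 2-fold apart and had several measured probe sets, of which 22 had a probe set short of 2-fold in that direction. These were HGF (-0.96), SOX6 (0.87), SOX9 (-0.22), PTGES (-0.88), PTGS2 (-0.86), HMGCS1 (0.82), IGFBP5 (0.82), IGFBP3 (-0.91), ECSCR (0.12) and SNAP25 (-0.22), with the log2 ratio of that probe set, and 12 whose probe sets are given with their values. A ratio just past 2-fold was therefore not separated from the disagreement between probe sets.

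**Figure D1:**
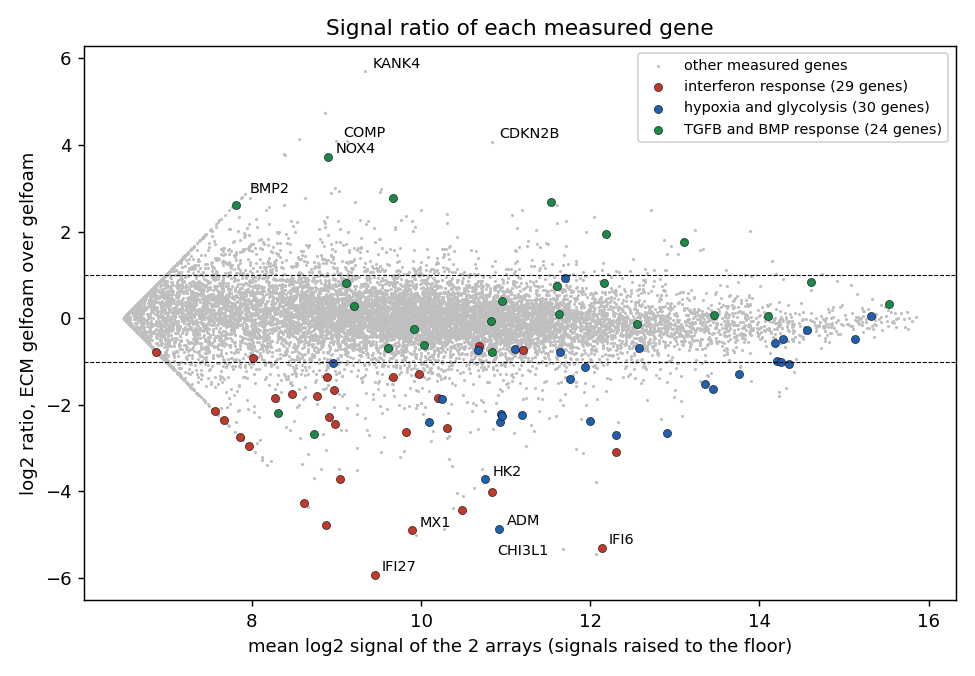
Log2 ratio of ECM gelfoam over gelfoam (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis) for 13236 measured genes, 1 point per gene, with dashed lines at 2-fold and coloured points for 3 gene lists. Members of the interferon list (29 genes) and 28 of 30 members of the hypoxia list lie below 0, while the TGFB and BMP list (24 genes) has 16 members above 0.

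Secreted osteogenic and angiogenic factors, a list wider than the osteogenic factors the series asked about, differed in both directions. The osteogenic members were not examined apart from the angiogenic ones. BMP2, a bone-inducing growth factor, was at least 6.97-fold higher on ECM gelfoam (624.2 against 82.7), and its 2 probe sets gave log2 ratios of 2.29 and 2.80. FGF1 was 3.59-fold, the cytokine gene IL11 3.01-fold, the procollagen protease gene BMP1 2.62-fold, PDGFA 2.48-fold, the placental growth factor gene PGF 2.11-fold and FGF9 at least 2.07-fold higher. In the other direction, hepatocyte growth factor (HGF) was 11.3-fold lower (155.2 against 1747), ANGPTL4 8.10-fold lower, GDF5 at least 7.57-fold lower and STC1 6.76-fold lower. VEGFA, the main angiogenic factor of the list and also a member of the hypoxia list, was 3.13-fold lower (6320 against 19773), with 4 probe sets between -1.69 and -0.12. FGF2 was 2.83-fold lower, and FGF5, SLIT3, ANGPT1, FGF7 and SLIT2 were 3.72, 3.08, 2.92, 2.68 and 2.19-fold lower. INHBA, among the brightest members, stood at 33465 against 18802 (1.78-fold higher). When centred on the poly-A controls, INHBA stood at -0.72, and BMP1, PDGFA, PGF and FGF9, which are 4 of the 7 higher factors, between -0.50 and -0.16. The value of FGF9 is a lower bound, since its gelfoam signal lay under the floor. BMP6 was near the floor on both arrays (92.8 against 114.7), and BMP4 and IGF1 were not above the floor on either.

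In all, 7 of 37 measured secreted factors were at least 2-fold higher and 11 at least 2-fold lower, where the upper end for matched random lists was 5 each way. Their median log2 ratio was -0.26, below the 95% range of matched random lists (-0.18 to 0.20; percentile 0.4 of 10000). That position did not hold under every setting: the median was 0.000443 with the mean or the median of a gene's probe sets and without probe sets marked as shared, and -0.025 with a pseudocount. Against random lists drawn under each of the 13 planned settings, it lay below their range in 6 and inside in 7. The 6 include trimmed mean scaling and the 2 centring settings. These left the percentile at 0.4 and so say nothing further about the position.

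**Figure D2:**
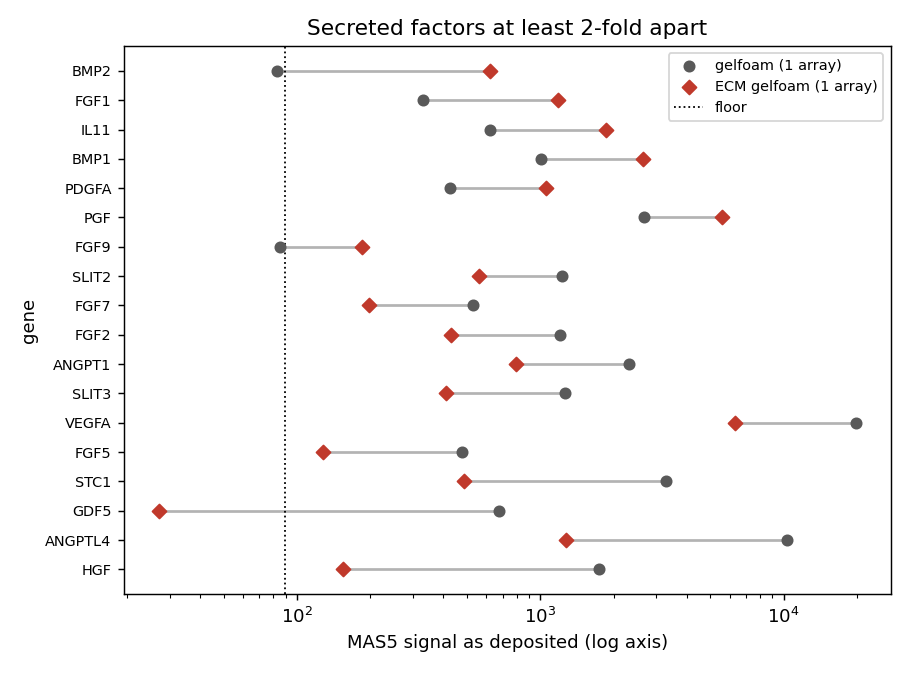
Deposited signal (log axis, arbitrary units) of the secreted factors at least 2-fold apart, with grey circles for the gelfoam array, red diamonds for the ECM gelfoam array and a dotted line at the floor of 89.6. The 7 upper genes, from BMP2 to FGF9, are brighter on ECM gelfoam, and the 11 lower genes, from SLIT2 to HGF, are dimmer there.

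Genes of the osteoblast lineage and mineralisation showed no common direction. The mineralisation inhibitor MGP was 2.20-fold higher on ECM gelfoam (1430 against 649.6) and S100A4 2.11-fold higher, and both stood below 0 when centred on the poly-A controls. TWIST1, a transcription factor that restrains osteoblast maturation, was 2.81-fold lower (2347 against 6584), and bone sialoprotein (IBSP) at least 2.05-fold lower. RUNX2, the osteoblast master regulator, had a log2 ratio of -0.36 (3536 against 4542), with probe sets from -1.31 to 0.37. Alkaline phosphatase (ALPL) stood at -0.91 (114.3 against 214.7) and osteopontin (SPP1) at 0.82 (619.5 against 351.3). SP7 was not above the floor on either array, and BGLAP had no probe set of its own. In all, 2 of 21 measured members were 2-fold higher and 2 were 2-fold lower, and the median of -0.07 lay inside the random range (-0.25 to 0.21).

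Interferon response genes were lower on ECM gelfoam throughout the list. All 29 measured members had log2 ratios below 0, 25 of them at least 2-fold lower, where the upper end for matched random lists was 4. Beside the genes named above, the ubiquitin-like modifier ISG15 was 8.53-fold lower (1729 against 14745), IFIT3 16.0-fold lower and MX2 13.1-fold lower, while GBP1 and IRF9 were 1.66-fold and 1.56-fold lower. The median log2 ratio was -2.36 against a random range of -0.20 to 0.29, below the medians of all 10000 matched lists. It was -1.56 with the mean of a gene's probe sets and -1.38 with a floor at the 75th percentile.

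Genes of hypoxia and glycolysis were also lower on ECM gelfoam. ADM (29.2-fold), hexokinase 2 (HK2, 13.2-fold), NDRG1 (6.53-fold) and the mitophagy gene BNIP3 (6.32-fold) differed most, although probe sets of HK2 ranged from -3.72 to -0.32. Glucose transporter genes SLC2A3 and SLC2A1 were 5.28-fold and 4.62-fold lower, and the pyruvate dehydrogenase kinase gene PDK1 5.24-fold lower. Very bright glycolytic enzymes differed less: ENO1 and PGK1 were 2.02-fold and 1.97-fold lower. Of 30 measured members, 19 were at least 2-fold lower, 0 were 2-fold higher and 28 lay below 0. The median was -1.22 against a random range of -0.28 to 0.05. The ratio of 3′ to 5′ signal of the array's GAPDH control, a sign of RNA integrity, was 3.35 on gelfoam and 1.54 on ECM gelfoam, and that of the ACTB control was 25.7 and 15.7. Signal at the 5′ end was thus weaker on both arrays, more so on gelfoam. Neither RNA can be taken as intact, and no fold in this report was corrected for it.

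Among matrix genes, 10 of 23 measured collagens were at least 2-fold higher on ECM gelfoam at the deposited scaling and 2 lower, where the upper end for matched random lists was 3 each way. COL5A3 was 7.62-fold higher (1448 against 190.1), COL7A1 of anchoring fibrils 5.61-fold higher (5558 against 990.9), COL10A1 4.64-fold higher and COL8A2 3.97-fold higher. The basement membrane collagens COL4A1 and COL4A2 were 2.49-fold and 2.15-fold higher, but stood at -0.23 and -0.44 when centred on the poly-A controls. COL1A1 read 50175 against 50430, near the highest signal of either array, where ratios can be compressed, and 1 of its 5 probe sets stood at 1.92. COL21A1 was at least 3.94-fold lower. The median of 0.12 lay just inside the random range (-0.26 to 0.13), with a mean of 0.51, and under 7 of 13 planned settings the median lay above the range of the setting (medians from 0.10 to 1.10). The median was -1.43 when centred on the poly-A controls, and 5 of the 10 higher collagens then stood below 0.

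Other matrix genes, proteases and receptors went both ways. Of 34 non-collagen matrix genes, 2 were 2-fold higher, the microfibril gene MFAP2 (4.72-fold) and the elastic fibre gene FBLN5 (2.89-fold). The latter stood at -0.019 when centred on the poly-A controls. A further 7 were 2-fold lower, among them EFEMP1 (8.68-fold) and LAMA4 (4.98-fold, with probe sets from -2.32 to -0.25). Their median was 0.02 and their mean -0.15, so the signs differed, and the median lay inside the random range (-0.26 to 0.07). Of 34 matrix proteases, inhibitors and crosslinkers, 8 were 2-fold lower and 1 higher. These included ADAMTS1 (5.26-fold lower), ADAMTS5 (3.48-fold lower), cathepsin K (CTSK, 2.86-fold lower) and LOXL4 (2.71-fold lower). Their median of -0.30 lay below the random range (-0.24 to 0.10). Among 22 integrins and matrix receptors, ITGB8 was at least 8.54-fold lower and SDC4 3.09-fold lower, while SDC1 was 3.44-fold higher. The median of that list was -0.06, inside the range of -0.29 to 0.16, and 0.03 after removal of a loess trend.

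Genes that respond to TGF-beta and BMP mostly lay within 2-fold (16 of 24), with a list median above its random range at the deposited scaling. Beside NOX4, the activin antagonist FSTL3 was 6.88-fold higher (2131 against 309.8) and PMEPA1 6.47-fold higher (7563 against 1169). The BMP targets ID1 and ID3 were 3.86-fold and 3.40-fold higher. The BMP antagonist NOG was 6.34-fold lower (169.8 against 1076). Of 24 measured members, 6 were 2-fold higher and 2 lower, with a median of 0.30 above the random range of -0.27 to 0.15, or -1.25 when centred on the poly-A controls. The contractile and YAP response list had 6 of 23 members 2-fold higher and 0 lower, with 15 above 0 and 8 below. It mixes contractile genes with YAP targets, so its median does not describe the YAP targets alone. CCN2 (3.02-fold), MYL9 (2.81-fold), CNN1 (2.58-fold) and ANKRD1 (2.57-fold) led it, the last 3 of which stood below 0 when centred on the poly-A controls. The second probe set of MYL9 stood at 0.23. Its median of 0.38 lay above all 10000 matched random lists (range -0.27 to 0.13), and was -1.17 when centred on the poly-A controls. In the Wnt list, DKK2 was 8.26-fold higher and LEF1 2.99-fold higher, while SFRP1 was at least 5.55-fold lower and FZD1 3.72-fold lower. There, 3 of 22 members were 2-fold higher and 2 lower, with a median of 0.35 (range -0.26 to 0.24), or -1.20 when centred on the poly-A controls. The Wnt median was 0.19 with no floor and no filter and with a pseudocount, and lay inside the range of the setting in 3 of 13.

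Cell cycle and growth genes differed in both directions. Proliferation genes were lower on ECM gelfoam in 30 of 35 cases, with 4 past 2-fold: TOP2A (2.31-fold), CDK1 (2.27-fold), HMMR (2.16-fold) and BIRC5 (2.05-fold). Probe sets of BIRC5 ranged from -1.10 to 0.64 and those of CDK1 from -1.18 to -0.04, and further ones of TOP2A and HMMR stood at -0.74 and -0.52. The median of this list was -0.49 (random range -0.25 to 0.12), below all 10000 matched lists. In the p53 and senescence list, CDKN2B, IGFBP5 (4.13-fold), PLK3 (2.45-fold) and CDKN2A (2.28-fold) were higher, and IGFBP3 was 3.27-fold and LMNB1 2.42-fold lower. Within 2-fold, CDKN1A, MDM2 and SESN1 had log2 ratios of 0.05, 0.16 and 0.04, and TP53I3 and GADD45A of 0.71 and 0.64. That list had 4 of 18 members 2-fold higher and 2 lower and a median of 0.28 (range -0.32 to 0.14), or -1.27 when centred on the poly-A controls, where PLK3 and CDKN2A also stood below 0. Insulin-like growth factor binding proteins, 3 of which belong to both lists, had 3 of 6 members 2-fold lower (IGFBP3, IGFBP2 and IGFBP6) and IGFBP5 higher, with a median of -0.98 (range -0.48 to 0.26). Planned settings moved that median of 6 genes as far as -0.38, and it lay inside the range of the setting in 2 of 13. Immediate early genes had a median of -0.44 (range -0.29 to 0.25), with EGR3 2.48-fold lower as the only 1 of 19 past 2-fold. Cholesterol synthesis genes were higher in 14 of 17 cases, with HMGCS1 (2.22-fold) and SQLE (2.03-fold) past 2-fold. The median of the cholesterol list was 0.59 (range -0.31 to 0.25), or -0.96 when centred on the poly-A controls, where both genes stood below 0.

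Surface and lineage markers of stromal cells also differed. PDGFRA was 13.7-fold lower on ECM gelfoam (1156 against 15893), the adhesion molecule gene VCAM1 15.2-fold lower (405.6 against 6176) and MME 9.84-fold lower (95.4 against 938.5). CSPG4, a pericyte marker, was 2.19-fold higher, or below 0 when centred on the poly-A controls. Stromal surface markers had 4 of 16 members 2-fold lower and 1 higher and a median of -0.42 (range -0.32 to 0.12), but 0.029 without probe sets marked as shared, and inside the range of the setting in 4 of 13. Chondrogenic markers had 3 of 10 members 2-fold higher, COMP, SOX6 (3.42-fold) and CILP (at least 2.06-fold). Centred on the poly-A controls, CILP stood at -0.50 or higher, a lower bound that leaves its sign open. SOX9 was 2.26-fold lower, and the median of 0.32 lay inside the range of -0.36 to 0.52. Adipogenic markers had 3 of 18 members 2-fold higher and 4 lower (median -0.15, range -0.23 to 0.31). FABP4 and FABP5 (2.97-fold) were higher, PLIN2 was 5.00-fold and CEBPD 4.42-fold lower, and PPARG was dim on both arrays (under the floor at 17.2 against 161.4). A further probe set of PLIN2 gave 0.05. In the PPAR response list, which shares FABP4, PLIN2 and LPL with the adipogenic one, 3 of 9 members were 2-fold higher and 3 lower, PDK4 by at least 3.80-fold (median -0.09, range -0.43 to 0.38).

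Inflammatory cytokines and chemokines had 6 of 21 members 2-fold lower and 2 higher, where the upper end for matched random lists was 3. Beside VCAM1, the prostaglandin synthesis genes PTGES and PTGS2 were 5.90-fold and 4.95-fold lower, and TNFAIP6, an anti-inflammatory hyaluronan-binding protein gene, was 4.11-fold higher (5328 against 1295). Their median of -0.12 lay inside the random range (-0.18 to 0.30), but ran from -0.72 to -0.06 over the 13 planned settings and lay below the range of the setting in 8. Markers of other cell types were few and mostly dim. Of 7 measured macrophage and leukocyte markers, the antigen presentation genes CD74 (at least 10.4-fold) and HLA-DRA (at least 2.39-fold) were lower on ECM gelfoam, and FCER1G was 2.00-fold higher (median -0.11, range -0.36 to 0.57). Osteoclast markers had 1 of 6 members higher (SIGLEC15, 2.24-fold) and CTSK lower (median 0.12, range -0.45 to 0.56). Endothelial markers had ECSCR at least 2.02-fold higher among 6 (median 0.25, range -0.38 to 0.60). Over the planned settings, medians ran from -0.38 to 0.19 for leukocyte, -0.40 to 0.75 for osteoclast and -0.0065 to 1.21 for endothelial markers. They left the range of the setting in 2 of 12, 1 of 13 and 2 of 12. FCER1G and SIGLEC15 stood below 0 when centred on the poly-A controls, as did ECSCR, whose value is a lower bound. Neural and epithelial markers had KRT14 3.15-fold higher and SNAP25 2.27-fold lower among 5 (median 0.14, range -0.51 to 0.63). Of 3 measured erythroid markers 0 were 2-fold apart, with HBB at 230.3 against 182.9 and AHSP at 108.6 against 94.9 (median 0.19, range -0.69 to 0.90).

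Stress, ribosomal and mitochondrial genes lay close to equality. Of 26 genes of the unfolded protein and amino acid responses, CEBPB was 2.04-fold lower and 0 were 2-fold higher (median -0.18, range -0.27 to 0.14). In the heat shock and oxidative stress list, GPX3 was 3.39-fold higher among 16 (median 0.09, range -0.33 to 0.16). All 7 metallothioneins lay below 0, MT1M 2.44-fold lower, with a median of -0.28 inside the range of -0.42 to 0.16. RPLP2 was 2.27-fold lower among 21 cytoplasmic ribosomal protein genes (median -0.13, range -0.29 to 0.02). Mitochondrial oxidative phosphorylation had 0 of 23 members 2-fold apart, with COX7A2 and COX7C at -0.14 and -0.36 (median -0.14, range -0.30 to 0.04). Housekeeping genes had 0 of 25 members 2-fold apart, with ACTB (also near the highest signals) at 0.27 and B2M at -0.44 (median -0.06, range -0.30 to 0.04, or 0.04 after quantile normalization). Of the 32 lists, 8 medians lay below and 5 above their 95% range, where 1.6 would lie outside by chance if lists moved no more than random genes. That position held under all 13 planned settings for 3 of the 8 (interferon, hypoxia and proliferation), for 3 of the 5 (TGFB and BMP, cholesterol, and p53 and senescence) and, wherever there was a value, for 13 of the 19 inside. Of these settings, trimmed mean scaling and the 2 centring settings left the percentiles as they were.

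**Figure D3:**
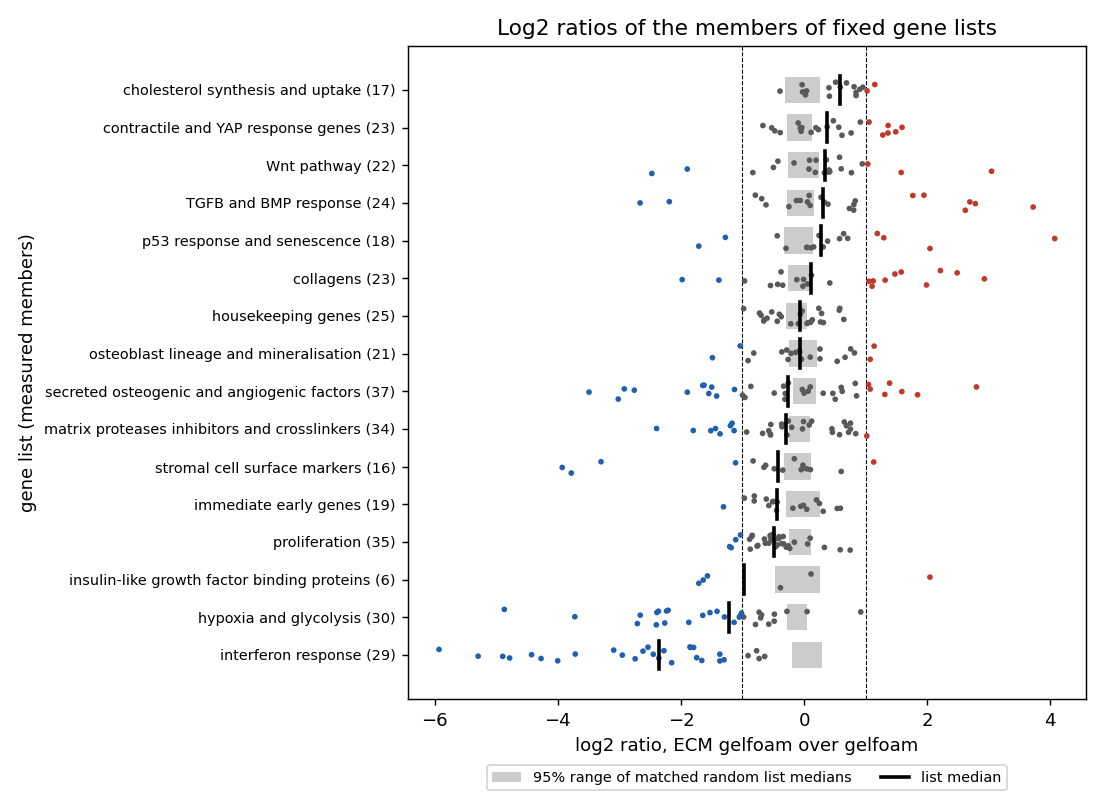
Log2 ratios of ECM gelfoam over gelfoam (horizontal axis) for the members of 16 gene lists (measured members in parentheses), 1 point per gene, red when at least 2-fold higher and blue when at least 2-fold lower. Black bars mark list medians and grey bands the 95% range of matched random lists: the interferon median (-2.36) and hypoxia median (-1.22) lie farthest to the left and the cholesterol median (0.59, or -0.96 when centred on the poly-A controls) farthest to the right.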

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

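The 3 tests on the interferon and hypoxia genes and the 2 tests on the poly-A controls were chosen after their results were seen, as was the loess comparison of the unnamed probe sets, whereas the 2 other tests on the unnamed probe sets were fixed before theirs were computed.

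Interferon response and hypoxia genes were lower on ECM gelfoam, with list medians of -2.36 and -1.22. The list median closest to 0 under any rescaling was still -1.16. Trimmed mean scaling and the 2 centring settings could hardly move the lists, so they do not bear on scaling. After quantile normalization and after loess, medians were -2.44 and -2.54 for interferon and -1.18 and -1.18 for hypoxia. These lay below their random ranges, so scaling was argued against only as far as these 2 settings can remove it. Leukocytes in the plain culture stayed open. Of 20 leukocyte markers with a value, only 7 passed the floor on either array, and 5 were bright enough on gelfoam for the test. Among the 5, CD74 and HLA-DRA were 2-fold lower on ECM gelfoam and 3 were above 0, with a median log2 ratio of 0.50 and an SD of 1.83. RNA integrity also stayed open, since gelfoam had the steeper 3′ to 5′ profile. The 3′ control probe sets differed by -0.18 for GAPDH and 0.28 for ACTB. They covered only 2 transcripts, fewer than the test required to argue against this explanation. Whatever their values, the test could therefore not have argued against it, and it decides nothing. A response to the matrix coating remains as an untested hypothesis, and with 1 array per condition it may equally be a difference between cultures, such as donor, cell density or oxygen, that the design leaves confounded with the coating.

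Probe sets without a gene name, which entered no comparison of the report, stood out because 959 of them were at least 2-fold higher on ECM gelfoam and 82 lower. Among the 4547 measured ones, 21.1% were 2-fold higher, against 8.19% of named probe sets of the same signal (upper end of 1000 matched draws 8.86%), and after removal of a loess trend 13.8% (628, with 2.93% lower), against an upper end of 4.93%, so a shift of dim signals was argued against as the whole cause. Genomic DNA in the ECM gelfoam sample could raise sequences outside named genes, and would raise 54 markers of other cell types as much. Their median log2 ratio without a floor was 0.37, inside the ranges of both unnamed (0.25 to 0.95) and named (-0.0037 to 0.68) probe sets of the same signal, so this test left the explanation open. Unspliced RNA and probe position were not tested, and no biological explanation was tested.

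The bacterial poly-A controls, which are added to the RNA and also entered no comparison, had a median log2 ratio of 1.55 (2.93-fold brighter on ECM gelfoam, 8 probe sets at the 3′ end of 4 controls between 0.91 and 1.74). A brighter hybridisation of that array was argued against, since the highest of 18 hybridisation control probe sets stood at -0.018 and their median at -0.18. Middle poly-A probe sets lay between 1.40 and 2.00, with those of the lys, phe and thr controls under the floor on gelfoam. The 5′ ones, all under the floor on at least 1 array, lay between -1.39 and 4.84. No floor was applied to these ratios. Another ratio of control mix to sample RNA stayed open. The 4 controls ranged from 2.04-fold (phe) to 3.16-fold (thr), with an SD of 0.29 inside the range of 0.14 to 1.35 for random sets of 4 genes. Probe sets of the same gene differed by an SD of 0.52, so even 1 shared ratio need not give an SD below 0.14. The test could therefore not decide, and it did not use the shift common to the 4 controls. Less sample RNA, less messenger RNA in it or more control mix were not told apart, and no biological explanation was tested.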

How the results depend on the processing

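No paired analysis was possible because each group has 1 array, and for the same reason leave-one-out settings and other splits of the samples were not possible. Signal over background limits the dim genes: 129 of the higher and 109 of the lower genes had 1 side under the floor. Over the 13 planned settings, 321 list medians stayed within the spread of random lists, 85 moved and 4 reversed, and of the named genes 1268 values stayed within the SD between probe sets, 125 moved and 0 reversed. Reversed means that a median outside its random range, or a gene at least 2-fold apart, changed sign. Medians inside their range changed sign 36 more times, in 12 lists with medians of at most 0.32 either way. A few lists had no value with a floor at the 75th percentile or without shared probe sets. The deposited signals already had equal trimmed means, and scaling to them again gave 690 and 694 genes. Unless stated, the cause of a move was not tested.

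The counts moved with settings of the floor and filter. Higher and lower genes numbered 1909 and 1214 with a floor at the 25th percentile, 250 and 395 at the 75th percentile, 3105 and 1874 with no floor and no filter, and 1627 and 1084 with a pseudocount. The lower floor measured 17559 genes and the last 2 settings 19740, in place of 13236. No floor with a filter on mean signal measured 12438 and gave 778 and 719. Under the other planned settings both counts stayed within 1.5 times 689 and 694. The share of higher genes, 49.8% as reported, was 36.4% after quantile normalization, 35.7% after loess, 61.1% and 38.8% with the lower and higher floor, 62.4% without floor and filter and 60.0% with a pseudocount.

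The secreted factor median of -0.26 was -0.091 with no floor and no filter and -0.025 with a pseudocount. It reversed to 0.000443 with the mean of probe sets, with their median and without shared probe sets, where the middle member was GDF10, at the floor on gelfoam. The interferon median of -2.36 was -2.62 with the lower floor and with no floor and no filter, -1.38 with the higher floor, -2.58 with no floor and a signal filter, -2.54 after loess, and -1.56 and -1.63 with the mean and median of probe sets. The hypoxia median of -1.22 was -1.13 with a pseudocount, -1.11 and -1.09 with the mean and median of probe sets and -1.83 without shared probe sets. The stromal surface median of -0.42 reversed to 0.029 without shared probe sets. Set against random lists of each setting, which was done after seeing the data, 3 of 8 lists below their range, 3 of 5 above and 13 of 19 inside kept that position wherever they had a value. Collagens lay above in 7 settings and inflammatory genes below in 8. Adipogenic and leukocyte markers lay below in 2 each, endothelial markers above in 2 and osteoclast markers above in 1. The 2 centring settings cannot change this position, and trimmed mean scaling, already met by the deposited signals, left the percentiles as they were.

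Centring on the 3′ probe sets of the poly-A controls, added after seeing the data, subtracts 1.55 from every log2 ratio. Counts became 31 higher and 11115 lower, and medians -1.80 for secreted factors, -3.91 for interferon and -2.76 for hypoxia. Of the 689 higher genes, 470 stood below 0, some of them as lower bounds because gelfoam lay under the floor. Of 13 medians that changed sign, the 5 above their random range reversed to -1.20 for Wnt, -1.25 for TGFB and BMP, -1.17 for contractile, -0.96 for cholesterol and -1.27 for p53 and senescence genes. Of the genes named by rule, log2 ratios reversed to -0.41 for MGP, -0.47 for S100A4, -0.019 for FBLN5, -0.50 for CILP, -0.059 for MYL9, -0.18 for CNN1, -0.19 for ANKRD1, -0.40 for HMGCS1, -0.52 for SQLE, -0.42 for CSPG4, -0.25 for PLK3, -0.55 for FCER1G, -0.39 for SIGLEC15 and -0.54 for ECSCR. Of the examples at least 2-fold higher that were named after their values were seen, BMP1, PDGFA, PGF, FGF9, COL4A1, COL4A2, CDKN2A and CD55 also stood below 0. The centred values of CILP, ECSCR and FGF9 are lower bounds, since gelfoam lay under the floor, so their signs are not settled.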

Other observations

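The 3 hypotheses below arose from single genes seen in the data, and each was tested on the other members of a list written before those members were looked at. They remain hypotheses, since they were found and tested on the same 2 arrays.

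Genes of antigen presentation may be lower on ECM gelfoam as a group, beyond CD74, HLA-DRA, HLA-DPA1 and B2M, from which the idea came. Of 20 other measured members, 13 were at least 2-fold lower and 0 were 2-fold higher, and their median log2 ratio was -1.11, against -0.26 to 0.25 for matched random lists. The immunoproteasome subunit gene PSMB9 was 8.37-fold lower (307.1 against 2572), the peptidase gene ERAP1 3.63-fold, the peptide transporter gene TAP1 3.41-fold and the class I gene HLA-E 2.81-fold lower. The class II regulator CIITA was not lower (115.0, against a signal under the floor), and HLA probe sets can bind related genes. Many of these genes are known interferon targets, so the list is not independent of the interferon result.

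Complement genes may also be lower on ECM gelfoam, an idea that came from C1R (10.6-fold lower) and SERPING1 (12.9-fold lower). Over 10 other measured members the median was -0.39, just below the random range of -0.36 to 0.42, with 3 members 2-fold lower and 1 higher. CFI was 7.02-fold lower, CFB at least 4.65-fold lower and C1S 3.20-fold lower, while the complement-restraining gene CD55 was 2.14-fold higher, or below 0 when centred on the poly-A controls. Whether the complement list is independent of the interferon result was not tested.

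A common direction of Notch pathway genes was not borne out. The ligand gene JAG1 (5.61-fold), HEY1 (6.15-fold), HES4 (at least 5.89-fold) and DTX4 (at least 6.80-fold) were higher on ECM gelfoam, and the target HES1 was 4.50-fold higher (1383 against 307.5). Over 16 members not seen beforehand, however, the median was 0.00619 (random range -0.27 to 0.30), with 8 above and 8 below 0, and HES1 was the only 1 past 2-fold. NOTCH3, NRARP and HEY2 stood at 0.77, 0.75 and 0.53, and RBPJ, MAML2 and MAML3 at -0.72, -0.55 and -0.49. The list mixes receptors, cofactors and targets, so its median does not describe the targets alone.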
